A study of Rattus norvegicus with 20 samples.

How the data were processed

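Gene expression was measured in cultured rat progenitor cells and their treated derivatives on 20 Affymetrix rat arrays with 8799 probe sets each. The deposited table gives a linear intensity for each probe set and array. The arrays look scaled to a common level, which is inferred from their trimmed means. After 2% of the values at each end are left out, the mean of an array lies between 200.3 and 200.5, while array medians run from 41 to 57.5. The steps upstream of this scaling, such as background correction and the way probes were summarised, are not given in the sources used here, and neither are detection calls. The number of arrays limits the precision.

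The labels give 4 groups. High-density progenitors (HD) have 6 arrays, low-density CCg progenitors (LD) have 4, LD cells treated with FBS to derive astrocytes have 6 (FBS), and LD cells treated with RA/Fsk to derive neurons have 4 (RA/Fsk). The labels do not expand CCg. FBS, RA and Fsk are the common abbreviations of fetal bovine serum, retinoic acid and forskolin. Arrays of a group that share a number in their labels were averaged on the log2 scale and are called a culture, which gave 3 HD, 3 LD, 4 FBS and 4 RA/Fsk cultures. The labels do not say whether the numbers stand for separate cultures, so the p-values measure the spread between these samples. The labels of the HD arrays do not mention CCg, so a difference between HD and LD cannot be assigned to density or to CCg.

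Intensities were transformed as log2(intensity + 4.99), where 4.99 is 10% of the median positive value of 49.9. The table holds 6 zeros and no negative values. The 59 control probe sets were left out, and 8740 were tested. As the annotation was read, 7006 of these carry a single gene symbol, 308 carry several and 1426 carry none, which covers 4736 genes. A # sign was read as the start of a comment, so probe sets with # in their identifier lost any symbol they had. Of the gene identifiers, 6985 were found in the RefSeq gene table of assembly GRCr8, and 0 symbols changed. Probe set identifiers are not printed because they contain sequence accessions.

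All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 10 residual degrees of freedom and a prior of 6.13. The comparisons were HD against LD, FBS against LD, RA/Fsk against LD and RA/Fsk against FBS. Differences are given as log2 of the group named first minus the group named second, with the standard error (SE). A probe set passed at a Benjamini-Hochberg adjusted p under 0.05 over the 8740 probe sets, and the words rose, fell and changed are used only for what passed. The median SE of a difference was 0.30 log2 for HD against LD, 0.28 for both treatments against LD and 0.26 for RA/Fsk against FBS.

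The 27 gene lists were tested with camera at a preset correlation of 0.01 between genes, using for each gene its probe set with the highest mean, and adjusted over the 108 tests of 4 comparisons. Camera with an estimated correlation and fry were run beside it. Groups, comparisons, tests, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule took, for each comparison, the 8 largest rises and the 8 largest falls among probe sets with a single symbol that passed, whose brighter group lay at or above the median of all values and whose cultures did not overlap between the groups. It also took up to 4 members of each list with the smallest adjusted p and a few set markers. Set markers without a probe set of their own in the annotation as read include Gfap, Tubb3, Sox2 and Mki67. The genes in the text were picked from those named by the rule after their values were seen. Genes given only to name the members of a small count, and the genes that moved in opposite directions with the treatments, were chosen after their values were seen.

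The fit was tested on simulated data with the spread of these cultures, in 5 runs with 200 of 8740 probe sets changed. For HD against LD, 5.07% of changes of 0.5 log2, 41.5% of changes of 1 log2 and 91.5% of changes of 2 log2 were recovered. For FBS against LD the shares were 8.36%, 44.2% and 96.1%, for RA/Fsk against LD 4.48%, 49.0% and 94.2%, and for RA/Fsk against FBS 11.6%, 46.6% and 96.7%. False calls made up 5.33%, 4.48%, 5.54% and 5.81% of calls in that order, and 0 had the wrong sign. In the data 75, 2225, 721 and 1606 probe sets changed in that order. The adjusted cut-off loosens as more probe sets change, so the recovered shares need not hold for the real comparisons. A list shifted by 0.5 log2 was called in 5 of 5 runs, and 0 unshifted lists were called for HD against LD. The simulated probe sets varied independently of each other. These runs therefore do not measure how often camera calls an unshifted list whose genes vary together.

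The same numbers recur in several groups, so deviations from the group means were correlated between cultures of a shared number. RA/Fsk and LD cultures of the same number gave r = 0.327, 0.157 and 0.108 across probe sets, and 6 of 6 cultures correlated best with their own number. The numbers may therefore pair these groups, which the labels do not say. The highest r belongs to number 1, whose LD and RA/Fsk cultures had the highest 5S rRNA control signal in their groups. A shared array effect could not be told apart from pairing. For HD against LD r was 0.143 and 0.090, with 3 of 4 cultures, so pairing stays open there. No clear pairing showed for FBS against LD (r = -0.063 to 0.099, 3 of 6) or RA/Fsk against FBS (r = -0.085 to 0.137, 3 of 8). The fit with the number as a replicate block was run as an alternative, and for RA/Fsk against LD its values are given where they change a result.

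Other alternatives were quantile normalization, median centring, other offsets, filters on low intensity, variance settings, a fit of 2 groups only, other ways to treat the arrays of a culture, the mean over the probe sets of a gene, and leaving out each culture. After the data were seen, 4 more were added. These left out array 3r of FBS culture 3, used only that array for the culture, took the ratio of the 5' to the 3' GAPDH control probe set as a covariate, or left out LD culture 1 and RA/Fsk culture 1 together, the cultures with the highest 5S rRNA control signal in their groups.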

Results

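Transcript levels were measured in rat progenitors at high density (HD), in low-density CCg progenitors (LD), and in LD cells treated with FBS or with RA/Fsk. Over the 20 arrays, 3 HD, 3 LD, 4 FBS and 4 RA/Fsk cultures could be compared. Arrays of the same culture correlated at r = 0.965 to 0.975 in HD, 0.952 in LD, and 0.951 and 0.975 in FBS. In FBS the lower value belongs to arrays 3 and 3r and lies below the 0.956 to 0.979 between different FBS cultures. Arrays of different groups correlated at 0.877 to 0.960. The first principal component held 37.9% of the variance and set the 4 FBS cultures (46.2 to 52.9) apart from the other 10 (-34.8 to -6.40). The second held 13.4%, and all 4 RA/Fsk cultures had positive scores on it (20.3 to 40.6).

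**Figure D1:**
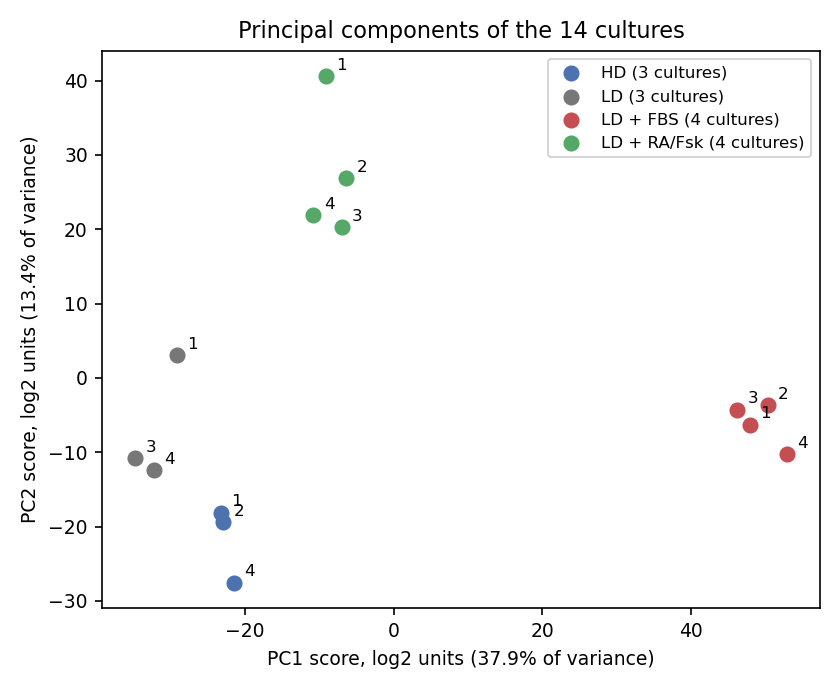
Scores of the 14 cultures on the first and second principal components of log2 intensity, with 37.9% and 13.4% of the variance, coloured by group and marked with culture numbers. The FBS cultures lie apart on the first component, at 46.2 to 52.9.

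The comparison of HD with LD asks how the progenitors differ between the 2 culture conditions. HD cells held more Aldoc, a glycolytic enzyme typical of astrocytes, more Cav1, the coat protein of caveolae, and more Abhd14b, a small hydrolase. Aldoc rose by 0.94 ± 0.17 log2 (SE, adjusted p = 0.0127), Cav1 by 1.77 ± 0.34 (adjusted p = 0.0156) and Abhd14b by 1.22 ± 0.22 (adjusted p = 0.0114). The falls were led by Rpl19l4, a gene like that of ribosomal protein L19, at -3.58 ± 0.34 (adjusted p = 0.000113), by Crp, which encodes C-reactive protein, at -2.61 ± 0.35 (adjusted p = 0.000916), and by Prrc2c, which encodes a large coiled-coil protein, at -1.90 ± 0.25 (adjusted p = 0.000758). Of the 2 other Crp probe sets, 1 passed. For each of these 6 genes the cultures of the 2 groups did not overlap. Without HD culture 4 the adjusted p was 0.0897 for Aldoc, 0.0922 for Cav1 and 0.0806 for Abhd14b. The Aldoc call also ended without LD culture 1 (0.0603). That of Cav1 ended without HD culture 2 (0.0811), LD culture 1 (0.0570) or LD culture 3 (0.0664). Over the alternatives the adjusted p ran from 0.000134 to 0.0897 for Aldoc, from 0.000475 to 0.122 for Cav1 and from 0.0013 to 0.141 for Abhd14b. Rpl19l4, Crp and Prrc2c passed under every alternative run. They also fell with FBS, at -4.72, -3.29 and -2.29, and with RA/Fsk, at -1.43, -1.16 and -1.11. The 27 probe sets without a single symbol described below had medians of -2.26 for HD, -2.53 for FBS and -1.12 for RA/Fsk against LD. Unspecific signal stays open for those and was not tested for Rpl19l4, Crp and Prrc2c, so what these named probe sets measure is uncertain.

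In all, 75 of 8740 probe sets changed between HD and LD, 38 up and 37 down, and 59 of them changed at least 2-fold. They include 15 named genes that rose and 7 that fell. The count was 23 without HD culture 4 (3 up and 20 down) and 33 without LD culture 3 (8 up and 25 down). It was 41 without HD culture 2 (18 up and 23 down) and 45 without LD culture 1 (17 up and 28 down). Without HD culture 1 it was 58 (26 up and 32 down), and without LD culture 4 it was 104 (56 up and 48 down). With the GAPDH 5' to 3' ratio as a covariate 23 rose and 56 fell. At an unadjusted p under 0.05 there were 1209, and 19.7% of probe sets had cultures that did not overlap, against 10% by chance. Of the 37 that fell, 27 carry no single gene symbol in the annotation as read, some of them with # in their identifier. Median centring moved the median difference of all probe sets from -0.08 to 0.02 log2. Of the 75 probe sets, 65 also changed the same way with FBS and 2 the opposite way. With RA/Fsk 35 changed the same way and 1 the opposite way. All 3 comparisons use the same LD cultures, so for these probe sets a feature of those cultures cannot be told apart from one of HD.

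Gene lists differed little between HD and LD, with medians of -0.21 to 0.27 in the 4 that were called. Proteasome subunits, which form the protease that degrades tagged proteins, had a median of -0.21 over 24 genes (adjusted p = 0.000293, adjusted p = 0.0685 with an estimated correlation). That call ended with the GAPDH 5' to 3' ratio, which differed by 0.26 log2 between HD and LD, as a covariate (0.105, with 9.17e-06 to 0.105 over the alternatives). Ribosomal protein genes had -0.15 over 45 (adjusted p = 0.000433, adjusted p = 0.587 with an estimated correlation), glycolysis and hypoxia genes 0.17 over 30 (adjusted p = 0.00352, adjusted p = 0.0639 with an estimated correlation), and cholesterol and fatty acid synthesis genes 0.27 over 22 (adjusted p = 0.00517, adjusted p = 0.606 with an estimated correlation). Over the alternatives the 4 medians ran from -0.25 to -0.11, from -0.25 to -0.05, from 0.10 to 0.27 and from 0.06 to 0.58 in that order. With fry, the ribosomal and cholesterol lists did not pass (0.111 and 0.564). The only single member to pass in these 4 lists was Rpl19l4, at -3.58 against the ribosomal median of -0.15, and what its probe set measures is uncertain as said above. Adjusted over the list alone, 4 glycolysis genes and 1 cholesterol gene rose, 2 ribosomal genes fell and 0 proteasome genes passed. In limma, 1209 probe sets of the array had an unadjusted p under 0.05. The cholesterol call ended without LD culture 1 (0.16) or HD culture 2 (0.154), with 5.03e-06 to 0.16 over the alternatives. That of the ribosomal list ended without LD culture 1 (0.0526), with 5.56e-06 to 0.054. The astrocyte list did not pass (adjusted p = 0.105).

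Treatment with FBS, given in the labels as the way to derive astrocytes, raised genes of the matrix and the cytoskeleton. Single astrocyte genes that rose include S100b, a calcium-binding protein, by 2.54 ± 0.18 log2 (adjusted p = 2.88e-08), Slc1a3, a glutamate transporter, by 1.97 ± 0.31 (adjusted p = 0.000117), and Glul, the glutamine synthetase, by 1.76 ± 0.17. The largest rises were in Igfbp2, a binding protein of insulin-like growth factors, at 6.16 ± 0.28 (adjusted p = 2.29e-10), Fn1, the matrix protein fibronectin, at 5.84 ± 0.29 (adjusted p = 4.9e-10), Anxa1, an annexin, at 5.76 ± 0.30 (4.80 to 6.19 over the alternatives), Cryab, a small heat shock protein, at 5.67 ± 0.17 (adjusted p = 1.91e-12), and Nog, a secreted inhibitor of BMP, at 5.46 ± 0.29 (4.48 to 5.89). Among the 8 largest falls were Rpl19l4 at -4.72 ± 0.32 (adjusted p = 1.76e-08), Coro1a, an actin-binding protein of leukocytes, at -3.93 ± 0.33 (-5.00 to -2.49), Lmnb1, a lamin of the nuclear envelope, at -2.96 ± 0.36, and Scd, a fatty acid desaturase, at -2.89 ± 0.35. What the Rpl19l4 probe set measures is as uncertain here as for HD. All 27 probe sets without a single symbol set beside it there also fell with FBS (median -2.53). For the 9 genes given among the largest rises and falls, cultures of the 2 groups did not overlap.

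FBS changed 2225 of 8740 probe sets, 1153 up and 1072 down, and 1322 changed at least 2-fold, 792 up and 530 down. Named genes numbered 642 up and 585 down, and 35.4% of probe sets had cultures that did not overlap, against 5.71% by chance. With median centring 976 rose and 1245 fell, so which direction holds the larger number depends on the scaling.

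Matrix and cytoskeletal genes made up the strongest rises among the lists. Of 53 extracellular matrix and adhesion genes, 27 rose and 1, Sdc1, fell (30 and 2 adjusted over the list alone), with a median of 0.85 (0.73 to 1.34 over the alternatives) and an adjusted p of 3.82e-10; Igfbp3 rose by 3.51 ± 0.21 and the integrin Itga1 by 3.26 ± 0.21. Of 34 actin cytoskeleton and serum response genes, 22 rose and 2, Actb and Csrp2, fell (23 and 2 adjusted over the list alone), with a median of 1.24 and an adjusted p of 3.7e-12; S100a4 rose by 4.39 ± 0.23 and Ccn1 by 4.07 ± 0.28. Both lists also passed with an estimated correlation (0.0338 and 0.0244). Among the list calls in all 4 comparisons, these 2 here, the same 2 between RA/Fsk and FBS, and the proteasome list between RA/Fsk and LD were the only ones that held with it.

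Most measured genes of the cell cycle and of cholesterol synthesis fell, although neither list held with an estimated correlation. Of 34 cell cycle genes, 30 fell and 0 rose (31 and 1 adjusted over the list alone), with a median of -1.43 and an adjusted p of 1.54e-16 (adjusted p = 0.216 with an estimated correlation). Dut, which keeps uracil out of DNA, differed by -2.39 ± 0.20, the DNA polymerase subunit Pold1 by -2.25 ± 0.24, the replicative helicase subunit Mcm6 by -2.03 ± 0.19 and the replication clamp Pcna by -1.36 ± 0.21. Of 12 genes of cell cycle exit, 6 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.66, with 0.42 to 0.91 over the alternatives, adjusted p = 0.00189, adjusted p = 0.216 with an estimated correlation), with Cdkn2b, a kinase inhibitor, at 2.46 ± 0.32. The 6 became 3 with median centring. Of 22 cholesterol and fatty acid synthesis genes, 17 fell and 0 rose (18 and 0 adjusted over the list alone, median -1.53, adjusted p = 5.4e-11, adjusted p = 0.223 with an estimated correlation). The 17 became 11 with the GAPDH 5' to 3' ratio as a covariate. Idi1, an isomerase of the mevalonate pathway, fell by 2.82 ± 0.24 and Acat2 fell by 2.74 ± 0.26.

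Of 45 ribosomal protein genes, Rpl19l4 among them, 40 fell with FBS and 0 rose, over all probe sets or adjusted over the list alone (median -0.91, adjusted p = 3.99e-21, adjusted p = 0.168 with an estimated correlation). The median was -0.57 with quantile normalization. Of 55 oxidative phosphorylation genes 27 fell and 0 rose (29 and 0 adjusted over the list alone, median -0.35, adjusted p = 7.72e-06, adjusted p = 0.231 with an estimated correlation). The 27 became 17 without LD culture 1, 14 without LD culture 3, 16 without FBS culture 1, 15 with array 3r alone, 16 without an intensity trend, and 12 with the GAPDH 5' to 3' ratio as a covariate. Of 24 proteasome genes 9 fell and 1, the immunoproteasome subunit Psmb8, rose, also when adjusted over the list alone (median -0.25, adjusted p = 0.00293, adjusted p = 0.145 with an estimated correlation). With that covariate the 9 became 5 and the call ended (0.053, with 0.000514 to 0.053 over the alternatives). The antisense control probe sets differed by -0.80 log2 between FBS and LD on average, the hexokinase control by 1.44 and the GAPDH 5' to 3' ratio by 0.27 (2-sided exact permutation p = 0.0286 for each, the smallest possible).

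The remaining list calls with FBS were rises, none of which held with an estimated correlation. The 41 interferon and antigen presentation genes had 15 up and 0 down, with the same counts adjusted over the list alone (median 0.34, with 0.11 to 0.89 over the alternatives, adjusted p = 0.000226, adjusted p = 0.274 with an estimated correlation), and Ifitm3, an antiviral membrane protein, rose by 4.02 ± 0.31. The 33 metallothionein and antioxidant genes had 14 up and 4 down (16 and 4 adjusted over the list alone, median 0.54, adjusted p = 0.0111, adjusted p = 0.216 with an estimated correlation), with the superoxide dismutase Sod3 at 3.77. The 4 down became 2 without LD culture 1, and the call ended with the dimmer 50% of probe sets left out (0.0901, with 0.00288 to 0.0901 over the alternatives). The 77 growth factor and receptor genes had 18 up and 3 down (19 and 3 adjusted over the list alone, median 0.23, adjusted p = 0.0119, adjusted p = 0.476 with an estimated correlation). That call ended with the GAPDH covariate, where the median was -0.04 and 5 fell, and with either filter on low intensity, with 0.00454 to 0.11 over the alternatives. The 25 immediate early genes had 9 up and 1, Myc, down, also adjusted over the list alone (median 0.27, with 0.18 to 0.75 over the alternatives, adjusted p = 0.0125, adjusted p = 0.216 with an estimated correlation), with the phosphatase Dusp1 at 2.41, and the call ended with the GAPDH covariate (0.051, with 0.00218 to 0.051 over the alternatives). The 31 genes of BMP, Notch and Wnt response had 9 up and 3 down (10 and 5 adjusted over the list alone, median 0.22, with 0.11 to 0.41 over the alternatives, adjusted p = 0.0176, adjusted p = 0.205 with an estimated correlation). The 3 down became 1 without LD culture 3, FBS culture 2 or FBS culture 3, 0 with array 3r alone or the GAPDH covariate, and 5 with quantile normalization. The call ended without LD culture 1 (0.0526) and with either filter on low intensity, with 0.00393 to 0.154 over the alternatives. Of 20 astrocyte genes 6 rose, S100b, Slc1a3, Glul, Aldoc, Mt3 and Agt, and 0 fell, also adjusted over the list alone (median 0.18, with 0.06 to 1.12 over the alternatives, adjusted p = 0.0395, adjusted p = 0.379 with an estimated correlation). This call ended without LD culture 1 (0.0526) or LD culture 4 (0.0611), with 0.0095 to 0.119 over the alternatives.

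Genes of neurons and oligodendrocytes moved both ways with FBS. Of 49 neuron genes 9 rose and 6 fell, also adjusted over the list alone; the secretory granule protein Chgb rose by 3.79 ± 0.43 (2.32 to 5.05 over the alternatives) and the calcium buffer Calb1 by 2.94 ± 0.37 (1.77 to 3.81), while the kinase subunit Camk2b fell by 1.46 ± 0.16. The 9 became 2 with the dimmer 50% of probe sets left out. Their median was -0.11, their mean 0.21 and the adjusted p 0.793. Of 18 oligodendrocyte lineage genes 3 rose and 2 fell (4 and 2 adjusted over the list alone), with a median of -0.09, a mean of 0.13 and an adjusted p of 0.834. Pdgfra, the receptor that marks oligodendrocyte precursors, fell by 2.51 ± 0.28, and the tetraspanin Cd9 rose by 2.86 ± 0.14. Of 19 neural progenitor genes Fgfr1 rose and 5 fell, Notch1, Hes5, Fabp7, Sox11 and Ptprz1, also adjusted over the list alone (median -0.14, adjusted p = 0.483). The 5 became 3 without LD culture 1, LD culture 3, FBS culture 2 or FBS culture 3, with array 3r alone and without an intensity trend. Fabp7, a fatty acid carrier of radial glia, fell by 1.79 ± 0.27. The retinoid and cAMP response lists did not pass with FBS. Of 26 retinoid response genes 8 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.169), and the 8 became 5 without LD culture 3 or the dimmer 50% of probe sets and 4 with the GAPDH covariate. Of 40 cAMP response genes 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.423). Of 60 genes of neuronal channels and receptors 6 rose and 3 fell (6 and 0 adjusted over the list alone, adjusted p = 0.9; the 3 became 0 or 1 without LD culture 4, FBS culture 1, FBS culture 3 or FBS culture 4 and 5 with each array as its own sample, quantile normalization or median centring), and of 17 Schwann and neural crest genes 4 rose and 1, Pou3f1, fell (5 and 1 adjusted over the list alone, adjusted p = 0.0915). Nes, which encodes nestin, differed by -0.02 (adjusted p = 0.972) and the water channel gene Aqp4 by -0.62 (adjusted p = 0.251), neither of which passed.

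**Figure D2:**
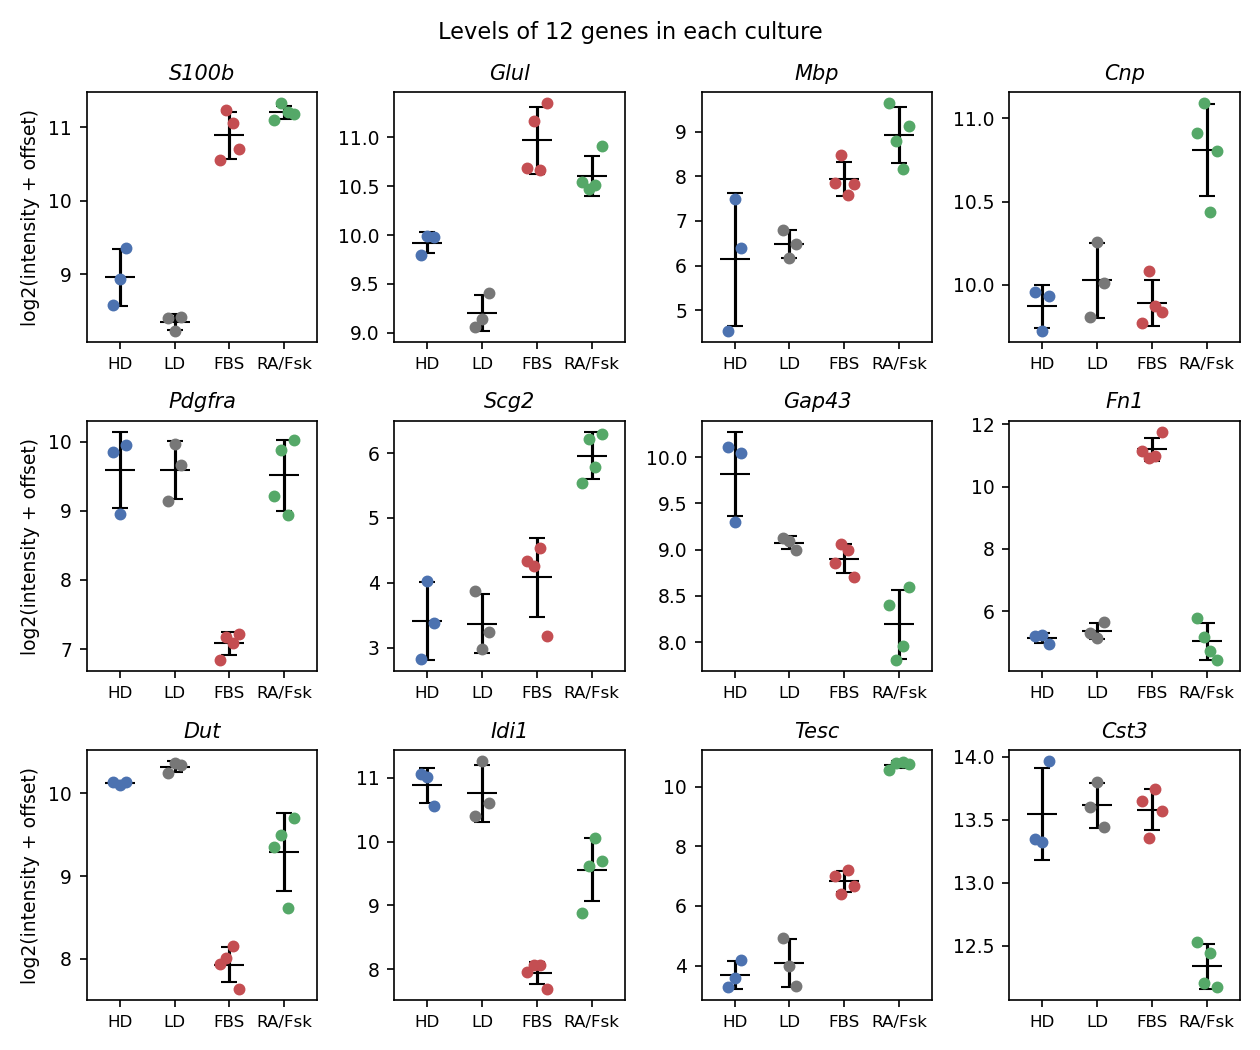
Log2(intensity + 4.99) of 12 genes in HD, LD, FBS and RA/Fsk cultures, with a point for each culture and bars for the mean and SD of 3, 3, 4 and 4 cultures. S100b is higher in both treated groups than in LD, by 2.54 with FBS and 2.85 with RA/Fsk, while Fn1 is higher in FBS by 5.84.

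Treatment of LD cells with RA/Fsk, given in the labels as the way to derive neurons, raised the calcium-binding protein gene Tesc most, by 6.65 ± 0.32 log2 (adjusted p = 1.29e-09). Among the 8 largest rises were also the chemokine Ccl2 at 4.71 ± 0.27 (adjusted p = 1.34e-08), the cyclin Ccnd2 at 3.70 ± 0.32, Sod3 at 3.64 ± 0.36 and the transcription factor Egr2 at 3.31 ± 0.40. Falls were led by Thbs4, a thrombospondin, at -2.96 ± 0.32 (adjusted p = 2.04e-05), and Coro1a at -2.58 ± 0.33. S100b rose by 2.85 ± 0.18 (adjusted p = 4.03e-08) and the myelin gene Mbp by 2.45 ± 0.49 (adjusted p = 0.00442). Scg2, a granule protein of neuroendocrine cells, rose by 2.60 ± 0.38 (adjusted p = 0.000306, with a rise of 1.42 to 3.59 over the alternatives). The growth cone gene Gap43 fell by 0.88 ± 0.21 (adjusted p = 0.0121), and Map2, a microtubule protein of dendrites, differed by 0.20 (adjusted p = 0.668). Cst3, which encodes cystatin C, fell by 1.28 ± 0.17 (adjusted p = 0.000125). For the 7 genes given among the largest rises and falls, cultures of the 2 groups did not overlap.

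RA/Fsk changed 721 of 8740 probe sets, 412 up and 309 down, and 360 changed at least 2-fold, 231 up and 129 down. Named genes numbered 266 up and 157 down, and 15.5% of probe sets had cultures that did not overlap, against 5.71% by chance. With the replicate block 756 changed, 439 up and 317 down, and with only these 2 groups in the fit 362 changed, 249 up and 113 down. Leaving out LD culture 3 gave 326 up and 185 down, and leaving out RA/Fsk culture 1 gave 452 up and 380 down.

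Oligodendrocyte, Schwann cell and astrocyte genes were among the 8 list calls with RA/Fsk. Of 18 oligodendrocyte lineage genes 5 rose, Mbp, Cnp, Enpp2, Sirt2 and Cd9, and 0 fell, also adjusted over the list alone (median 0.23, with 0.17 to 0.58 over the alternatives, adjusted p = 0.000686, adjusted p = 0.231 with an estimated correlation). Of 17 Schwann and neural crest genes 7 rose and Gap43 fell, also adjusted over the list alone (median 0.47, with 0.28 to 0.64 over the alternatives, adjusted p = 0.000433, adjusted p = 0.216 with an estimated correlation). The 7 include S100b, Mbp, Cnp, Egr2 and Cryab, which other lists hold too. Of 20 astrocyte genes S100b, Glul and Aldoc rose, or 5 without LD culture 1, and 0 fell (5 and 0 adjusted over the list alone, median 0.16, with 0.09 to 0.35 over the alternatives, adjusted p = 0.0122, adjusted p = 0.274 with an estimated correlation), and without RA/Fsk culture 2 the adjusted p was 0.0615, with 0.00339 to 0.0938 over the alternatives. Of 34 cell cycle genes 19 fell and 0 rose (28 and 0 adjusted over the list alone, median -0.82, adjusted p = 7.28e-16, adjusted p = 0.216 with an estimated correlation). The 19 became 11 without LD culture 3, 12 without an intensity trend, 10 with 2 groups only in the fit and 6 without LD culture 1 and RA/Fsk culture 1 together. The polymerase gene Pola1 fell by 2.05 ± 0.35 and Dut fell by 1.03 ± 0.20. Of 12 exit genes Cdkn1b and Cdkn2b rose (4 adjusted over the list alone, median 0.33, with 0.18 to 0.42 over the alternatives, adjusted p = 0.0353, adjusted p = 0.359 with an estimated correlation). This call ended without LD culture 1 (0.326), RA/Fsk culture 3 (0.0921) or RA/Fsk culture 4 (0.0604), with 0.00844 to 0.326 over the alternatives.

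Sterol, ribosomal and proteasome genes were also called lower with RA/Fsk as lists, of which the proteasome list alone held with an estimated correlation. The proteasome list was also called lower than LD in HD and in FBS (medians -0.21 and -0.25). Between RA/Fsk and FBS it did not pass (median 0.07, adjusted p = 0.827). A feature of the shared LD cultures therefore cannot be told apart from an effect of RA/Fsk. The 22 cholesterol and fatty acid synthesis genes had a median of -0.69 (adjusted p = 0.000433, adjusted p = 0.511 with an estimated correlation). With fry this list did not pass (adjusted p = 0.102). Of its genes Fdps, Idi1, Dhcr7, Acat2 and Msmo1 fell and 0 rose, against 11 and 1 adjusted over the list alone. The 5 became 2 without LD culture 3, 3 without LD culture 4 or RA/Fsk culture 2, 15 without RA/Fsk culture 3, 8 with the replicate block, with culture as a random block or with each array as its own sample, 2 with median centring or 2 groups only in the fit, and 3 with array 3r alone, without LD culture 1 and RA/Fsk culture 1, or without an intensity trend. Fdps, a synthase of the mevalonate pathway, fell by 1.56 ± 0.28 and Idi1 fell by 1.19 ± 0.24. Of 45 ribosomal protein genes 11 fell and 0 rose, against 27 and 0 adjusted over the list alone, with a median of -0.38 (-0.44 to -0.20 over the alternatives, adjusted p = 2.92e-11, adjusted p = 0.274 with an estimated correlation). The 11 became 3 without LD culture 1, 4 without LD culture 3, 17 without RA/Fsk culture 1, 5 without RA/Fsk culture 2, 6 without RA/Fsk culture 4, and 5 with quantile normalization or median centring. They became 7 without array 3r and 4 with array 3r alone, although it is in neither group, and 2 to 23 over the alternatives as a whole. Of 24 proteasome genes Psma5, Psma7, Psmb4 and Psmc2 fell and 0 rose, against 13 and 0 adjusted over the list alone, with a median of -0.32 (adjusted p = 8.55e-06, adjusted p = 0.0338 with an estimated correlation). The 4 became 0 without LD culture 3, 1 without RA/Fsk culture 2, 2 without RA/Fsk culture 4, 1 with median centring or array 3r alone, 2 without LD culture 1 and RA/Fsk culture 1, 0 without an intensity trend or with 2 groups only in the fit, and 7 with the dimmer 50% of probe sets left out.

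Neuron genes did not move as a list with RA/Fsk. Of 49 measured, Scg2, Scg3 and Rab3a rose and Gap43 fell, also adjusted over the list alone (median 0.06, adjusted p = 0.644). Rab3a, which acts in vesicle release, rose by 1.21 ± 0.28 (adjusted p = 0.0109), but not without LD culture 3 (0.0586, with 0.00244 to 0.0679 over the alternatives). Scg3 rose by 0.92 ± 0.27 (adjusted p = 0.0442). Its call ended without LD culture 1 (0.124), LD culture 3 (0.149), LD culture 4 (0.0553), RA/Fsk culture 2 (0.122) or RA/Fsk culture 4 (0.118), with 0.00773 to 0.155 over the alternatives. Of 60 genes of neuronal channels and receptors Cacna1d rose and Grin2a fell (0 and 0 adjusted over the list alone, median -0.13, adjusted p = 0.733), against 1840 probe sets of the whole array at an unadjusted p under 0.05 in limma. The Cacna1d call ended without LD culture 1 (0.147), LD culture 3 (0.148), RA/Fsk culture 1 (0.0632), RA/Fsk culture 2 (0.0842) or RA/Fsk culture 4 (0.092), and that of Grin2a without LD culture 1 (0.161), LD culture 4 (0.0797), RA/Fsk culture 2 (0.0878) or RA/Fsk culture 3 (0.0759) and with the replicate block (0.0562). Over the alternatives the adjusted p ran from 0.0188 to 0.188 for Cacna1d and from 0.0106 to 0.161 for Grin2a. Of 26 retinoid response genes 5 rose, Hoxa5, Dusp6, Plat, Ntrk2 and Nr2f1, and 0 fell (5 and 1 adjusted over the list alone), with a median of -0.03, a mean of 0.17 and an adjusted p of 0.358. The homeobox gene Hoxa5 rose by 1.52 ± 0.21 and the nuclear receptor gene Nr2f1 by 1.39 ± 0.21. Of 40 cAMP response genes Crem, Pde4b, Fos, Scg2 and Npy rose and Dusp1 and Vip fell (7 and 2 adjusted over the list alone, median 0.06, adjusted p = 0.372), and the 5 became 3 without LD culture 3 or with 2 groups only in the fit. The neuropeptide gene Vip fell by 1.60 ± 0.26 (-2.54 to -0.70 over the alternatives) and the cAMP phosphodiesterase gene Pde4b rose by 1.09 ± 0.20.

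**Figure D3:**
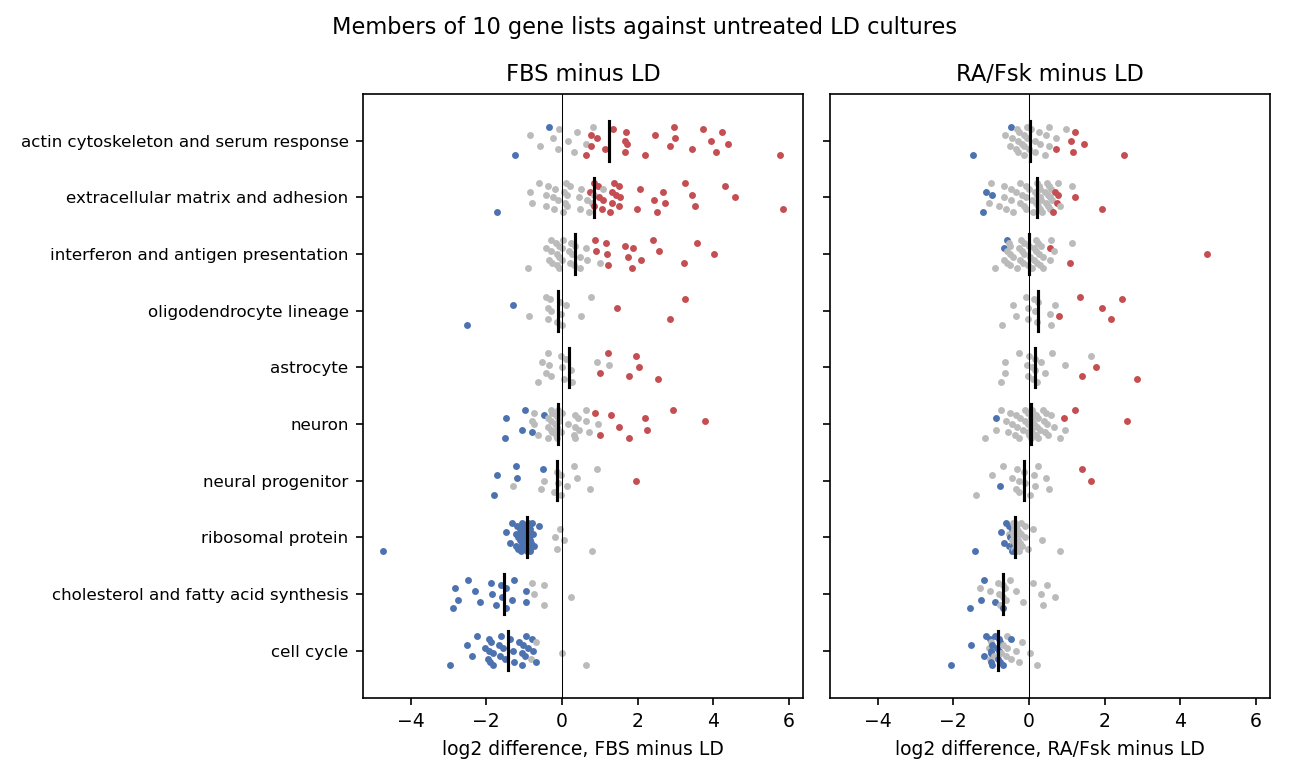
Log2 difference from LD of each measured member of 10 gene lists with FBS and with RA/Fsk; red points rose, blue points fell, grey points did not pass, and the black line is the median of the list. The cell cycle median is -1.43 with FBS and -0.82 with RA/Fsk.

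The treatments were also compared directly, which asks where the derivatives differ from each other. The largest falls from FBS to RA/Fsk were in the matrix protein gene Fn1 at -6.17 ± 0.26 log2 (adjusted p = 2.35e-10), the annexin gene Anxa1 at -5.80 ± 0.28, the growth factor binding protein gene Igfbp2 at -5.42 ± 0.26 and the BMP inhibitor gene Nog at -4.84 ± 0.27. Among the 8 largest rises were Tesc at 3.91 ± 0.30, Ccl2 at 3.54 ± 0.25, Lgr5, a receptor that boosts Wnt signalling, at 3.21 ± 0.35, and the proteoglycan Cspg5 at 2.77 ± 0.28. Fabp7, the fatty acid carrier, rose by 2.23 ± 0.25 and the growth factor receptor gene Pdgfra by 2.43 ± 0.26, while neither the neural progenitor list (adjusted p = 0.733) nor the oligodendrocyte lineage list (adjusted p = 0.0661) passed. S100b differed by 0.31 (adjusted p = 0.237) and Map2 by 0.23 (adjusted p = 0.51), which did not pass, while the glutamate transporter Slc1a3 fell by 1.76 ± 0.28. In all, 1606 probe sets differed, 723 up and 883 down, and 802 at least 2-fold, 251 up and 551 down. Named genes numbered 424 up and 491 down, and 21.5% of probe sets had cultures that did not overlap, against 2.86% by chance. Median centring moved the median of all probe sets from 0.06 to 0.16 log2 and gave 852 up and 688 down, so the direction of the larger number depends on the scaling.

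Of the 10 lists called between RA/Fsk and FBS, 2 held with an estimated correlation. The extracellular matrix and adhesion list had 28 down and 1, Itgb3, up, also adjusted over the list alone (median -0.63, with -1.06 to -0.49 over the alternatives, adjusted p = 5.08e-12), and the actin cytoskeleton and serum response list had 24 down and 0 up, also adjusted over the list alone (median -1.03, adjusted p = 3.9e-16). Interferon and antigen presentation genes had 17 down and 1, Ccl2, up (19 and 2 adjusted over the list alone, median -0.60, with -0.90 to -0.40 over the alternatives, adjusted p = 2.4e-05, adjusted p = 0.231 with an estimated correlation). Genes of BMP, Notch and Wnt response had 11 down and 1, Ccnd1, up (11 and 2 adjusted over the list alone, median -0.17, with -0.30 to -0.07 over the alternatives, adjusted p = 0.00242, adjusted p = 0.0907 with an estimated correlation), and 7 down without FBS culture 1 or FBS culture 4. That call ended with the dimmer 50% of probe sets left out (7 down, 0.0825, with 0.00045 to 0.0825 over the alternatives). Growth factor and receptor genes had 17 down and 4 up (18 and 5 adjusted over the list alone, median -0.23, adjusted p = 0.0161, adjusted p = 0.5 with an estimated correlation), a call that ended with the GAPDH covariate and with either filter on low intensity (0.0041 to 0.222 over the alternatives). The 17 became 11 with that covariate, where the median was 0.02, and 10 with the dimmer 50% of probe sets left out.

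Cell cycle, sterol and ribosomal genes were called higher in RA/Fsk than in FBS as lists, though not with an estimated correlation. Cell cycle genes had 17 up and 1, Id2, down (23 and 1 adjusted over the list alone, median 0.59, adjusted p = 1.02e-07, adjusted p = 0.379 with an estimated correlation), and 26 up without RA/Fsk culture 3. Cholesterol and fatty acid synthesis genes had 12 up and 0 down (17 and 0 adjusted over the list alone, median 0.85, with 0.56 to 1.03 over the alternatives, adjusted p = 1.45e-08, adjusted p = 0.274 with an estimated correlation). Ribosomal protein genes had 36 up and 0 down (37 and 0 adjusted over the list alone, median 0.57, adjusted p = 2.93e-16, adjusted p = 0.216 with an estimated correlation). Oxidative phosphorylation genes had 11 up and 0 down (14 and 0 adjusted over the list alone, median 0.23, adjusted p = 5.78e-05, adjusted p = 0.274 with an estimated correlation), 7 up without FBS culture 1, 17 without array 3r, 6 with array 3r alone or without an intensity trend, and 3 with the GAPDH covariate. Between RA/Fsk and FBS the hexokinase control differed by -0.81 log2, the B1 repeat by 0.73 and the antisense controls by 0.42 (2-sided exact permutation p = 0.0286 for each, the smallest possible), and the GAPDH 5' to 3' ratio by -0.24 (exact p = 0.0571). Genes of cell cycle exit had 4 down and 0 up (6 and 1 adjusted over the list alone, median -0.52, adjusted p = 0.0316, adjusted p = 0.351 with an estimated correlation). The 4 became 2 with median centring, and the call ended without RA/Fsk culture 1 (0.111) or RA/Fsk culture 2 (0.0514), with 0.00519 to 0.111 over the alternatives. Neuron genes had 8 up and 7 down (9 and 8 adjusted over the list alone), with a median of 0.12, a mean of -0.11 and an adjusted p of 0.934. The 8 became 5 with the GAPDH covariate, and the 7 became 2 with the dimmer 50% of probe sets left out. Astrocyte genes had Aldoc up and 4 down, Slc1a3, Clu, Mt3 and Agt, also adjusted over the list alone, with a median of 0.14, a mean of -0.12 and an adjusted p of 0.827. The 4 became 2 without FBS culture 2, RA/Fsk culture 1 or RA/Fsk culture 4, with the GAPDH covariate, with culture as a random block and with each array as its own sample.

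Many genes moved the same way with both treatments. Among the shared rises were Plat, a plasminogen activator (4.07 with FBS and 3.02 with RA/Fsk), Sod3 (3.77 and 3.64) and S100b (2.54 and 2.85). Among the shared falls were Coro1a (-3.93 and -2.58) and Idi1 (-2.82 and -1.19). In all, 306 probe sets rose with both treatments and 239 fell with both. The sum of 545 compares with 92.3 from the product of the shares, while 23 moved in opposite directions, against 91.3. These products assume independent comparisons, while both treatments are set against the same LD cultures, so they are not a chance level here. Log2 differences of the treatments correlated at r = 0.582 across probe sets, with a covariance of 0.291. In 100 simulations of unchanged groups that share the LD cultures the values were 0.572 and 0.0558. The observed correlation is therefore close to what shared LD cultures alone give, while the observed covariance is larger. The simulations gave 0 shared calls, so they hold no count to set against 545. The simulations hold no link by number between RA/Fsk and LD. The differences of both treatments use the same 3 LD cultures, which are too few to be divided between them.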

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

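The tests of the GAPDH ratio for the unnamed probe sets and for array 3r, and of an LD array under the label of 3r, were chosen after their results were seen, and so was the requirement that a value clear its bound by more than its spread, which left open the antisense test below and the scaling test of the ribosomal genes.

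Control signals that no comparison uses differed between HD and LD. Signals were higher in LD by 1.24 log2 for 5S rRNA, 0.88 for the B1 repeat, 1.26 for the B2 repeat and 0.73 for the mean of the antisense controls, and higher in HD by 1.32 for hexokinase (exact 2-sided permutation p = 0.1 for each, the smallest possible with 3 against 3 cultures). Between FBS and LD the hexokinase control differed by 1.44, 5S rRNA by -1.17 and the B1 repeat by -1.15 (exact permutation p = 0.0286 for each, the smallest possible). All 8 keep their sign with quantile normalization and with median centring.

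A first pattern lies beside the higher repeat, 5S rRNA and antisense signals in LD: 27 probe sets without a single gene symbol were lower in HD by a median of -2.26 log2 (-4.22 to -1.10). They were picked for having passed there, with no value computed for what that choice gives without a change; all 27 also fell with FBS (median -2.53) and 14 with RA/Fsk, against the same LD cultures. RNA integrity as read from the GAPDH 5' to 3' ratio is argued against as the whole cause: with it as a covariate the mean difference went from -2.25 ± 0.26 to -2.59 ± 0.30, and 23 of 27 still passed, while the ratio had a slope of its own in 19.6% of all probe sets. Unspecific signal in the antisense controls stays open: with that covariate the mean difference was -1.42 ± 0.45 and 0 of 27 passed, the smaller difference and its wider error both counting toward that. Density, CCg and, for FBS and RA/Fsk, the treatments are the biological differences the labels give. They were not tested apart and also stay open. What these probe sets measure is not known here, and some of them lost any symbol they had through the # in their identifier.

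A second pattern concerns FBS culture 3, whose GAPDH ratio lay -0.14 log2 away from the other FBS cultures because of array 3r. Arrays 3 and 3r differed by more than 1 log2 in 16.3% of probe sets, against 7.21% for arrays 1a and 1b. An LD array under its label is argued against, since 3r correlated at no more than 0.903 with any LD array and at 0.951 or more with the other 5 FBS arrays. A small admixture of LD RNA stays open: the difference of 3r from 3 followed LD minus FBS with a slope of 0.133 (bootstrap 95% interval 0.108 to 0.161 over 1996 probe sets), and that of 1a from 1b with 0.00325. The hexokinase control of 3r was 79.6, inside the LD range (38.4 to 111.9) and below the other 5 FBS arrays (200.6 to 297.3). Its antisense mean of 6.84 lay inside the LD range (6.70 to 7.23) and above those arrays (5.41 to 6.44). The B1 and B2 repeats of 3r (25.4 and 21.4) lay among those arrays. A small admixture alone would move a control only part of the way to LD. Lower RNA integrity also stays open, since 3r had a GAPDH ratio of 0.824. It lay below the other 5 FBS arrays in the GAPDH and the actin ratio by more than their range. The bootstrap interval measures the spread over probe sets of 1 pair of arrays, not the spread between samples. The GAPDH ratio was also higher in FBS than in LD by 0.27 log2, so the slope does not tell admixture from lower integrity. Either, or both, may hold, and no biological explanation was tested, since the labels give none.

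The last pattern weighed is the fall of ribosomal protein genes with FBS, at a median of -0.91. Compression of bright probe sets is argued against as the whole cause: the median lies at percentile 0 of 10000 random lists matched on level, whose medians ran from -0.81 to -0.03. Those lists drew their genes independently, so the percentile does not measure chance for genes that vary together. Compression stays open as a part of the cause, since the 203 other genes in the brightest 5% had a median of -0.24. Scaling between arrays stays open in part, because the median with quantile normalization was -0.57 with a bootstrap SD of 0.0773, which is not below -0.5 by more than that spread, while median centring gave a lower median than the deposited scaling. The treatment itself, the biological difference the labels give, remains possible and was not tested apart from these.

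Of 234 pairs of a gene and a treated group, 15 had a culture far from the other 3, and of 14 control values 2 did. The bound was the 95% critical value of Dixon's test, which chance passes in about 1 in 20 groups of normally distributed values. That rate was not measured here. RA/Fsk culture 3 holds 6 of them. In it Fdps lay 1.56 log2 above the mean of the other 3 cultures. Enpp2 lay at -1.70 from them. Pnlip lay at -1.77 there, and FBS culture 4 at -0.43 for the same gene. Ccnd3 lay at -0.80 and Lxn at -0.23. Anxa5 lay 0.34 above. RA/Fsk culture 4 stood out in Aldoc at 0.25 and in Glul at 0.41. RA/Fsk culture 1 stood out in Rab3a at -0.86 and in Scd2 at -0.87. FBS culture 1 stood out in Rpl19l4 at 0.85, FBS culture 2 in Nr2f1 at 0.71, FBS culture 3 in Cdkn1a at -0.31 and FBS culture 4 in Cyp51 at -0.40. The B2 control of FBS culture 4 lay at -1.40.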

How the results depend on the processing

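Without array 3r, with array 3r alone, with the GAPDH covariate, and without LD culture 1 and RA/Fsk culture 1, the tests were chosen after the data were seen. The counts for FBS against LD and for RA/Fsk against FBS stayed within 1.5 times their values under every alternative. For HD against LD, 75 became 465 with each array as its own sample, 252 with culture as a random block over 20 arrays (correlation 0.188) and 48 with array 3r alone, and leaving out each culture gave 23 to 104. For RA/Fsk against LD, 721 became 362 with 2 groups only in the fit, and leaving out each culture gave 511 to 832, against 1946 to 2028 for FBS against LD and 1293 to 1628 for RA/Fsk against FBS. Lists called for HD against LD went from 4 to 2 without LD culture 1 and RA/Fsk culture 1, to 2 with fry and to 0 with an estimated correlation; limma gave 1209 probe sets an unadjusted p under 0.05 there. With an estimated correlation the lists went from 14 to 2 for FBS against LD, from 8 to 1 for RA/Fsk against LD and from 10 to 2 for RA/Fsk against FBS. At an adjusted p under 0.01 the shared changes of the treatments went from 545 to 277. In FBS against LD, Cst3 and the heat shock list had no call to reverse. With quantile normalization Cst3 passed at 0.42 (adjusted p = 0.0363, against 0.0363 to 0.991 over the alternatives), and with fry, which asks another question than camera, the heat shock list was called up (0.0395). The cause was not tested for any of these. Of 231 named gene calls, 191 held under every setting: 3 of 16 for HD against LD, 84 of 88 for FBS against LD, 46 of 67 for RA/Fsk against LD and 58 of 60 for RA/Fsk against FBS. Of 36 list calls, 22 held under every setting of the same test, 1 of 4, 8 of 14, 6 of 8 and 7 of 10 in that order. The size of 60 of the 231 gene calls moved by more than 1.5 times under some alternative, 47 of them with an offset of 50% of the table median, 22 of these also without an offset, and 14 with the GAPDH covariate. Of 64 counts of 4 or more list members, 12 moved by more than 1.5 times with the dimmer 50% of probe sets left out, 11 with the GAPDH covariate, 11 without LD culture 3, 9 without an intensity trend, 8 with median centring and 8 with 2 groups only in the fit, and at most 7 under any other alternative. With the GAPDH covariate the cholesterol list in FBS against LD had 11 falls in place of 17, oxidative phosphorylation 12 in place of 27, and proteasome 5 in place of 9. With the replicate block 74, 2278, 756 and 1693 probe sets changed in the 4 comparisons. It ended the calls of Ifitm10 (0.0571), Sox11 (0.0711) and Grin2a (0.0562) in RA/Fsk against LD and no list call there. In the other comparisons it ended those of Mbp (0.0637) and the astrocyte list (0.0527) for FBS against LD. It also ended 6 gene calls for HD against LD, where the endoplasmic reticulum stress list (0.0114) and Fgfr1 (0.0451) came to pass. It changed no other call of a named gene. Lists were not tested with the random block or the robust variance. With no detection calls, signal over background could not be judged, so weak probe sets are limited by an unknown background.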

Other observations

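Single genes of cell contact changed with the treatments, but the list did not pass. Of 36 measured, 9 rose and 3 fell with FBS (9 and 4 adjusted over the list alone, with 2 to 5 falls over the alternatives, median 0.03, or -0.01 with quantile normalization and -0.06 with median centring, adjusted p = 0.483), and 5 rose and 1 fell with RA/Fsk (6 and 1 adjusted over the list alone, adjusted p = 0.421), where the 5 became 3 without LD culture 1 or LD culture 3 and 2 without RA/Fsk culture 2 or RA/Fsk culture 4, with 2 to 7 over the alternatives. Nrcam, an adhesion molecule of the axon, rose by 3.02 ± 0.30 log2 with FBS, and N-cadherin, the product of Cdh2, by 2.10 ± 0.35, while Cntn1, a contactin, fell by 1.61 ± 0.20. With RA/Fsk, Ntm, a neurotrimin, rose by 2.18 ± 0.30. Of 20 endoplasmic reticulum stress genes 8 rose and 3 fell with FBS (10 and 3 adjusted over the list alone, adjusted p = 0.209), and the 8 became 5 without LD culture 1 or with median centring and the 3 became 1 with the GAPDH covariate. Ppp1r15a, which restores translation after stress, rose with both treatments, by 1.96 ± 0.26 with FBS and 1.79 ± 0.26 with RA/Fsk, and the serine synthesis gene Psat1 fell by 1.41 ± 0.20 with FBS. Of 17 heat shock genes 5 rose and 4 fell with FBS (5 and 5 adjusted over the list alone), with a median of -0.23, a mean of 0.40 and an adjusted p of 0.979; the 5 became 3 without LD culture 1, LD culture 4 or FBS culture 2, with median centring or with the GAPDH covariate, and 2 with the dimmer 50% of probe sets left out. The chaperone Hspa1a rose by 2.78 ± 0.40 while mitochondrial Hspe1 fell by 0.94 ± 0.13.

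Some genes moved apart between the treatments. The phosphatase Dusp1 rose by 2.41 with FBS and fell by 1.57 with RA/Fsk, where its adjusted p of 0.0141 became 0.0746 without LD culture 4 and 0.0524 without LD culture 3 (0.000259 to 0.127 over the alternatives), and the direct comparison gave -3.98 ± 0.35. The kinase Pim3 rose by 1.06 with FBS and fell by 1.06 with RA/Fsk, under every alternative run. Bin1, a membrane-bending protein, fell by 1.08 with FBS and rose by 0.70 with RA/Fsk. Of 30 glycolysis and hypoxia genes 10 rose and 3 fell with FBS (11 and 3 adjusted over the list alone, adjusted p = 0.0851), and the 10 became 6 without LD culture 4 or FBS culture 4. The peptide hormone Adm rose by 3.72 (2.53 to 4.43 over the alternatives). Of 18 microglia and macrophage genes Ctss rose and Coro1a fell with FBS, also adjusted over the list alone (adjusted p = 0.912). Of 23 endothelial, mural and fibroblast genes Edn1 alone rose, or 3 genes without LD culture 1 (0 adjusted over the list alone, adjusted p = 0.979), and 0 passed with RA/Fsk, where limma gave 1840 probe sets of the array an unadjusted p under 0.05.

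The splits of the cultures into groups of the same sizes were planned tests. For FBS against LD the real split gave 2225 probe sets and the highest other 494. The values were 1606 and 1 for RA/Fsk against FBS, 721 and 251 for RA/Fsk against LD, and 545 and 346 for the overlap of the treatments. The splits for RA/Fsk against LD and for the overlap ignored the numbers that RA/Fsk and LD share. In each case only the real split gave so many, out of 35 splits, or 100 for the overlap. Chance is not excluded by that, because the other splits put the real group difference inside their groups. This widens the spread and lowers their counts. The splits of HD and LD are too few to tell for the probe sets, with 75 against 1. Of these 10 splits, 4 gave the real number of 4 lists, the real one included, so chance is not excluded for that number. For the number of lists called chance cannot be excluded, with 14 against 14 for FBS, 8 against 8 for RA/Fsk and 10 against 13 between the treatments. Among the 8 splits that part all 3 numbered pairs of RA/Fsk and LD, as the real one does, the highest other gave 0 probe sets and 6 lists, and 8 splits are too few for a share under 0.05. The splits with high counts for FBS place 3 LD cultures with 1 FBS culture, so they keep part of the real contrast, and single lists were not tested over splits.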
